A study of Mus musculus with 30 samples.

How the data were processed

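RNA sequencing of mouse cells was analysed in 30 libraries from 3 sources: sorted LSK cells (Lin- Sca-1+ Kit+, the compartment that holds stem and multipotent progenitor cells), bone marrow of mice with myeloid disease, and cultured stromal cells from compact bone. Per the labels, RNA was taken with TRIzol and libraries were made with the Illumina TruSeq stranded mRNA kit. Per the submitters' processing notes, the reads went through bcl2fastq, FastQC, TopHat, SAMtools and edgeR with the mm10 build, without versions. The counting program, annotation, low-value filter, library scaling and sex of the mice are not given in the sources used here.

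The deposited LSK and bone marrow values were handled as a normalised signal per gene. Their names call them CPM, but library totals ran from 803746 to 1437201, so the scaling was not by the plain library total. The choice of tests made before the data were examined had assumed CPM, and the same log-scale test was kept. The stromal values are TPM as deposited by the authors, and their totals of 924162 to 939600 show that part of each library was not in the table. In the bone marrow table every value was a whole multiple, within 0.05 of a read, of 1 step per library for 99.99 to 100% of values. Reads recovered from these steps numbered 17341986 to 21698808 per library. No such step was found in the LSK table, and TPM keeps no depth, so sequencing depth is unknown for those libraries.

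The tables held 11740, 11430 and 20619 genes for LSK, bone marrow and stromal cells. Among the bone marrow genes, 155 names that repeated another gene under an alias were merged into it, which left 11275. Of the names, 11327, 10972 and 19877 were found in the mm10 annotation used for positions and transcript lengths.

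Groups came from the labels alone. 4 LSK comparisons, a pair in bone marrow and 1 in stromal cells were each tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) on log2(value + 1), with a Benjamini-Hochberg threshold of 0.05. Fold changes are on this scale, which understates the change of genes with low values. Genes needed a value of at least 1 in as many libraries as the smallest compared group holds. The 4 LSK groups shared 1 estimate of the spread, and the AML comparison by exposure was fitted with all 12 marrow libraries.

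Of 36 gene lists fixed before any value was seen, those with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of each comparison. One list, of sex-linked genes, was only described. Each test was repeated with an estimated correlation. Counts of list members that passed are given over all genes and adjusted over the list alone. Shares of ribosomal protein, haemoglobin and mitochondrial transcripts were compared with two-sided exact permutation tests in SciPy 1.17.1 under Python 3.11.15. Tables were handled with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

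Genes named for a comparison follow a fixed rule. It takes Egr1, Apc and Trp53, then up to 8 passing genes per direction with the largest fold change, a mean of at least 5 in the higher group and no overlap between groups. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p and a mean of at least 5 are named as not passing. For each list described, up to 4 members with the smallest p are named. Predicted genes and pseudogenes without a standard name were passed over, and some genes that the rule selects are not reported here. Single libraries in bone marrow were described with further members of the fixed lists and a few lineage genes chosen after their values were seen.

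The alternatives were a pseudocount of 0.1, no filter, median-of-ratios rescaling, the replicate number as a block, leaving out each library in turn, and narrower or wider sets of groups. edgeR 4.0.16 (quasi-likelihood test) was run on the recovered marrow reads, and on no other table since no reads could be recovered there. Added after seeing the data were a term for 3 LSK libraries that stand apart, fits without libraries that stand apart, and a term for sex in stromal cells. Replicate numbers were checked as pairs by correlating the deviations of same-numbered libraries from their group means. In stromal cells these were 0.501, 0.674 and 0.718 for numbers 1, 2 and 3. The highest with another number was 0.144, 0.271 and -0.479. Each ENU library thus correlated best with the mock library of its number. With 3 per group such a match can arise by chance, and mock 3 and ENU 3 both stood apart. Whether these mice were paired is not given in the sources used here. In LSK cells and bone marrow not every library correlated best with its own number. The counts of calls with the block had been seen before these correlations were computed.

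The limma test of each comparison, and edgeR for AML against MDS, were tried on simulated data in which 200 genes were changed by 1, 2 or 3 on the log2 scale. The limma test recovered 10.7%, 63.2% and 78.9% of them for transplanted against untransplanted wild type, and 17.9%, 75.0% and 85.5% for EAP against transplanted wild type. It recovered 17.9%, 67.2% and 85.3% for EAP with ENU against EAP, and 16.7%, 61.7% and 82.4% for EAP with ENU against transplanted wild type. In bone marrow limma recovered 52.5%, 89.1% and 96.0% for AML against MDS. There edgeR recovered 20.5%, 97.3% and 100%, on separately simulated reads with a fixed spread not taken from the data. The shares of the 2 tests thus cannot be set against each other, and both simulations gave AML and MDS the same spread. For AML by exposure limma recovered 8.20%, 61.6% and 77.3%, and for stromal cells 47.7%, 68.1% and 86.4%. The camera test was tried for AML against MDS on simulated lists of which 1 was raised by 1 on the log2 scale. It made 1 call and 0 false ones. The permutation tests, camera in the other comparisons and edgeR for AML by exposure were not tried in this way. The limma tests made 2 to 9 false calls among 108 to 168 calls, and simulated genes varied independently, which real genes do not. For limma and edgeR the changed genes were drawn only from those above a minimum mean. The recovered shares thus do not cover genes with low values. p-values measure only the spread between these libraries.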

Results

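The 30 libraries cover a mouse model of therapy-related myeloid neoplasms on the C57BL/6 background. LSK cells came from 4 groups of 3: untransplanted wild type (WT), wild type marrow transplanted with a luciferase shRNA (transplanted WT), marrow haploinsufficient for Egr1 and Apc with a Trp53 shRNA (EAP), and the same with ENU, an alkylating mutagen, given to donor and recipient (EAP with ENU). Cells were sorted about 2 months after transplantation, before disease. Bone marrow came from 6 mice with MDS and 6 with AML. Stromal cells at passage 1 to 2 came from 3 mock-treated mice and 3 given 100 mg/kg ENU 1 month earlier. Summed values per library were 808377 to 1437201 for LSK cells, 803746 to 1118648 for bone marrow and 924162 to 939600 TPM for stromal cells. The marrow libraries held 17341986 to 21698808 recovered reads, and depth is unknown for the other libraries. Libraries are named by group and replicate number.

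Trp53, the tumour suppressor targeted by the shRNA, lies on chromosome 11 at 69580359 to 69591873 in mm10. Its values in LSK cells were 349, 213 and 339 in WT 1 to 3, 308, 370 and 247 in transplanted WT, 65.5, 132 and 106 in EAP, and 70.6, 173 and 76.1 in EAP with ENU. The 6 libraries with the Trp53 shRNA thus lay at 65.5 to 173 and the 6 without at 213 to 370, with no overlap. The means were 101 ± 33.3 (SD, n = 3) in EAP and 308 ± 61.9 in transplanted WT, a log2 difference of -1.64 ± 0.38 (SE) that did not pass (adjusted p = 0.655). Against the same controls EAP with ENU gave -1.63 ± 0.38 (adjusted p = 0.732). In bone marrow, Trp53 was 97.9, 92.7, 43.1, 57.4, 72.2 and 45.4 in MDS 1 to 6 and 58.0, 23.0, 33.4, 26.3, 27.0 and 50.2 in AML 1 to 6. In stromal cells it was 108, 112 and 83.0 in mock and 117, 117 and 111 in ENU.

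Egr1, an immediate early transcription factor, lies on chromosome 18 at 34859823 to 34864984. It was 167, 212 and 174 in WT, 188, 137 and 133 in transplanted WT, 75.0, 840 and 329 in EAP, and 308, 57.7 and 77.4 in EAP with ENU. In marrow, Egr1 was 160, 201, 135, 220, 597 and 306 in MDS 1 to 6 and 227, 539, 181, 340, 190 and 910 in AML 1 to 6. In stromal cells Egr1 was 122, 56.2 and 646 in mock and 128, 55.5 and 362 in ENU.

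Apc, a negative regulator of Wnt signalling, lies on chromosome 18 at 34220924 to 34322552. It was 13.4, 4.23 and 10.9 in WT, 6.13, 8.15 and 4.31 in transplanted WT, 5.41, 8.82 and 11 in EAP, and 7.79, 6.51 and 7.21 in EAP with ENU. In marrow, Apc was 84.3, 87.9, 101, 108, 82.2 and 117 in MDS 1 to 6 and 73.7, 150, 125, 125, 122 and 141 in AML 1 to 6. In stromal cells Apc was 23.4, 23.2 and 20.4 in mock and 24.8, 24.2 and 22.6 in ENU. None of the 7 comparisons moved Egr1, Apc or Trp53 past the threshold as planned. Without AML 1, Trp53 (-1.05, adjusted p = 0.0216) and Apc (0.46, adjusted p = 0.0297) passed in AML against MDS. The Egr1 and Apc values do not separate haploinsufficient from wild type libraries, and a mutant allele can still give transcripts counted to its gene. The library EAP 1 carries a transplant label of wild type marrow against its other labels, and its Trp53 value of 65.5 is the lowest of the 12 LSK libraries.

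**Figure D1:**
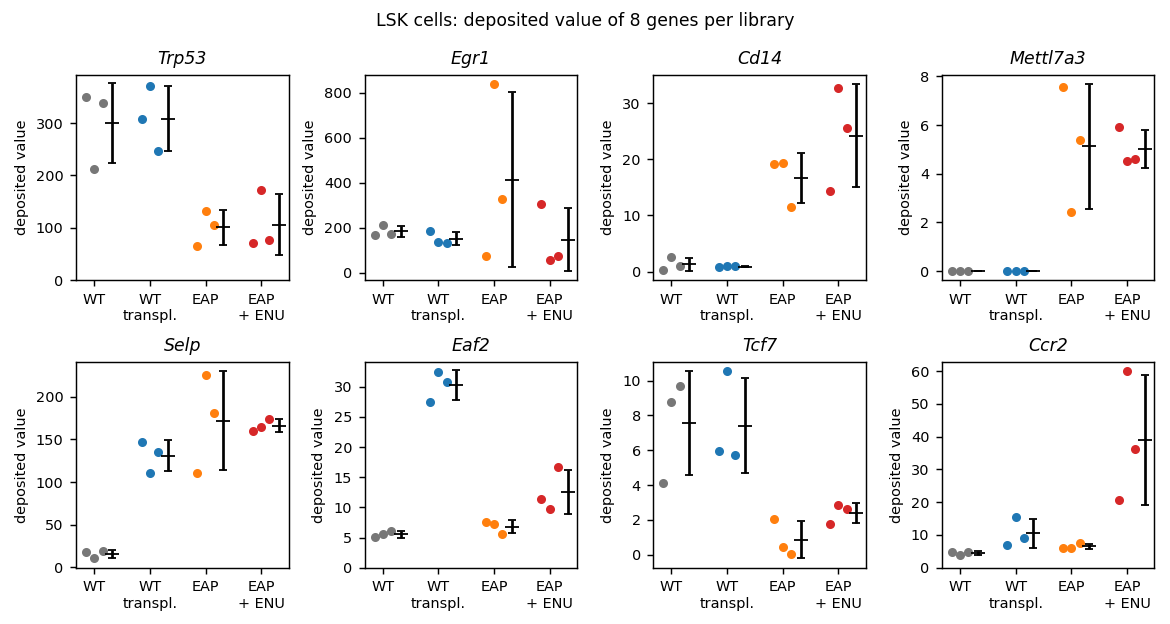
Deposited values (y axis, normalised signal) of Trp53, Egr1, Cd14, Mettl7a3, Selp, Eaf2, Tcf7 and Ccr2 in each LSK library (points, 3 per group), with the group mean and SD as bars. Trp53 lies at 65.5 to 173 in the 6 shRNA libraries and at 213 to 370 in the 6 others.

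Transplanted WT was set against untransplanted WT to ask what transplantation with a control vector alone changed, since both went together. Selp, which encodes the platelet and endothelial adhesion molecule P-selectin, rose from 15.6 ± 4.35 to 131 ± 18.4 (SD, n = 3 each), a log2 change of 3.02 ± 0.29 (SE, adjusted p = 0.00385). Eaf2, a transcription elongation factor, rose from 5.56 ± 0.562 to 30.2 ± 2.5 (2.25 ± 0.26, adjusted p = 0.0130). Ndn, an imprinted growth suppressor used in mouse haematology as a stem cell gene, fell from 13.3 ± 3.46 to 0.997 ± 0.277 (-2.82 ± 0.36, adjusted p = 0.0273). These 3 of 11730 genes passed, with no overlap between groups for each, while 855 had an unadjusted p under 0.05 and 16.1% of genes were fully separated against 10% by chance. Selp passed without each of the 6 libraries in turn (adjusted p = 0.0159 to 0.0409), but not in a fit of these 2 groups alone (0.158). Eaf2 and Ndn stayed past the threshold only without WT 2 (0.0223 for both). Eaf2 lost its call without WT 1 (0.127), WT 3 (0.0833), transplanted WT 1 (0.0670), 2 (0.156) or 3 (0.109). Ndn lost its call without WT 1 (0.178), WT 3 (0.213), transplanted WT 1 (0.0893), 2 (0.247) or 3 (0.177), and with a pseudocount of 0.1 (0.336).

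Next in line, and not passing, were Emilin2, a matrix glycoprotein gene (47.1 against 9.04, adjusted p = 0.105), and Jchain, the immunoglobulin joining chain (584 ± 342 against 23.9 ± 28.8, adjusted p = 0.121). Gstm7 stood at 6.57 against 1.78. Slc35d3 stood at 7.83 against 32.9, Mmp2 at 7.19 against 23.3 and Rftn2 at 0.923 against 9.14. Each of these 4 had an adjusted p of 0.223. With a term for 3 LSK libraries that stood apart, chosen after the data were seen, all 6 passed (adjusted p = 0.00849 for Jchain to 0.0221 for Gstm7) and the count of genes went from 3 to 275. Without these libraries all 6 passed too (0.0159 for Emilin2, Jchain and Rftn2 to 0.0388 for Gstm7), and without WT 2 alone Jchain (0.0160) and Rftn2 (0.0219) did.

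Several lineage gene lists were higher after transplantation, as tests of the list as a whole. Of 31 lists, 18 passed, and 0 of 31 did so with an estimated correlation. Eosinophil, basophil and mast cell markers had a median log2 change of 1.87 (adjusted p = 5.35e-09; adjusted p = 0.0765 with an estimated correlation). Leaving out 1 library moved their mean from 1.77 without transplanted WT 3, which stood apart and lay 1.08 above its group here, to 2.60 without transplanted WT 1. Among them Mcpt8, a basophil protease, was 83.5 ± 41.7 against 13.4 ± 3.20, and Prg2, the eosinophil major basic protein, was 76.3 ± 61.7 against 3.53 ± 2.63. Of this list 0 members passed over all genes and 4 adjusted over the list alone, which include Fcer1a (15.1 against 0.416) and Prss34 (264 against 18.1). Myeloid progenitor granule and growth factor receptor genes had a median change of 1.0 (adjusted p = 2.5e-07; adjusted p = 0.139 with an estimated correlation). Elane, neutrophil elastase, was 499 ± 271 against 34.2 ± 18.1, Ctsg, cathepsin G, was 317 ± 50.3 against 70.4 ± 30.8, and Ms4a3 was 63.6 against 7.11; of this list 0 members passed over all genes and 5 adjusted over the list alone. Megakaryocyte markers had a median change of 0.47 (adjusted p = 0.000192; adjusted p = 0.0765 with an estimated correlation). In this list Gp5 was 39.6 ± 11.2 against 11.6 ± 6.09 and Gp1ba was 8.98 against 2.51, both platelet glycoproteins, with 1 member past the threshold over all genes and 6 adjusted over the list alone.

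Mitosis genes had a median change of 0.53 (adjusted p = 1.99e-08; adjusted p = 0.0765 with an estimated correlation). Ube2c, which drives exit from mitosis, was 255 ± 2.05 against 120 ± 4.14, and Aurkb was 224 ± 53.2 against 113 ± 3.60; 0 passed over all genes and 2 adjusted over the list alone. Stem cell genes moved the other way, with a median of -0.33 (adjusted p = 0.000344; adjusted p = 0.197 with an estimated correlation). Their mean ranged from -0.61 without WT 2 to -0.26 without transplanted WT 3. Besides Ndn, this list held Gprasp2 (5.22 against 10.4) and Mllt3 (8.01 against 13.3). In it 1 member passed over all genes and 2 adjusted over the list alone. Late neutrophil markers (median 1.29), T and NK cell markers (0.62), MHC class II (1.27), histone transcripts (0.61) and erythroid markers (0.50) also passed as higher, with an adjusted p of 1.68e-06, 2.40e-06, 2.59e-05, 0.00166 and 0.00102. With an estimated correlation the adjusted p was 0.0765 for late neutrophil markers and 0.139 for the other 4. Over all genes 0 of their members passed, and adjusted over the list alone 4, 3, 4, 1 and 1 did. The mean of T and NK cell markers went from 0.83 to 0.54 without transplanted WT 2. H2-Eb1 was 79.0 ± 51.4 against 14.2 ± 6.18, Ngp was 6.28 against 0.453 and Hba-a1 was 27.8 against 6.49. Erythroid markers did not pass without the libraries that stood apart (0.0572).

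The other 8 passing lists each lost their call without at least 1 of the 6 libraries. DNA replication (0.32, adjusted p = 0.00119) and oxidative phosphorylation (0.48, 0.000754) were higher, and did not pass without transplanted WT 3 (adjusted p = 0.136 and 0.114). With an estimated correlation their adjusted p was 0.396 and 0.532. Type I interferon response genes (-0.15, adjusted p = 0.0189) were lower, with Ifit3 at 9.79 against 21.3, and lost the call without WT 3 (0.0542) or transplanted WT 3 (0.521). Lymphoid priming genes (-0.58, adjusted p = 0.0189) were lower, with Satb1 at 46.9 against 86.0, and lost it without WT 1 (0.180), WT 3 (0.131) or transplanted WT 1 (0.0848). Both had an adjusted p of 0.368 with an estimated correlation. Leukaemia-associated progenitor regulators (-0.37, adjusted p = 0.0189) lost the call without WT 1 (0.0518) or transplanted WT 3 (0.177), and cholesterol synthesis genes (-0.29, adjusted p = 0.0199) without WT 2 (0.437) or transplanted WT 1 (0.0523). Their adjusted p was 0.312 and 0.347 with an estimated correlation. Monocyte and macrophage markers (0.35, adjusted p = 0.0161) lost it without WT 1 (0.0609) or transplanted WT 2 (0.101), and osteoblast genes (0.45, adjusted p = 0.0446) without WT 1 (0.153), WT 3 (0.102), transplanted WT 1 (0.0790) or 2 (0.135). With an estimated correlation their adjusted p was 0.197 and 0.161. In these 8 lists 0 members passed over all genes and 0 adjusted over the list alone. B cell markers (median 0.01, mean -0.06, tested as lower, adjusted p = 0.788), p53 targets (median -0.06, adjusted p = 0.689) and DNA repair genes (0.12, adjusted p = 0.475) did not pass.

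EAP was set against transplanted WT to ask what the combined Egr1, Apc and Trp53 losses changed before disease; genotype and knockdown go together. Cd14, the lipopolysaccharide co-receptor of monocytes, rose from 0.913 ± 0.0895 to 16.7 ± 4.47 (SD, n = 3 each), a log2 change of 3.18 ± 0.41 (SE, adjusted p = 0.0262). Eaf2 fell from 30.2 ± 2.5 to 6.78 ± 1.10 (-2.01 ± 0.26, adjusted p = 0.0262). Its mean in untransplanted WT, given above, was lower still. Mettl7a3, a methyltransferase-like gene with near-identical neighbours whose reads may be shared, was listed at 0 in the 3 transplanted WT libraries and the 3 WT libraries and lay at 2.45 to 7.55 in EAP (adjusted p = 0.0262). These 3 of 11730 genes passed, against 424 at an unadjusted p under 0.05, and 6.98% of genes were fully separated against 10% by chance. Without any 1 of the 6 libraries Cd14 did not pass (adjusted p = 0.0735 to 0.206, and 0.116 with a pseudocount of 0.1), nor did Eaf2 (0.0704 to 0.209), and Mettl7a3 passed only without EAP 2 (0.00552; 0.0704 to 0.206 without the others). In a fit of these 2 groups alone 0 genes passed. Without EAP 1 and the other libraries that stood apart Cd14, Mettl7a3 and Eaf2 gave 0.0640, 0.107 and 0.0640. With a term for those libraries, also chosen after the data were seen, they passed (0.00859, 0.0128 and 0.00859).

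Genes next in line that did not pass were Hyi, a hydroxypyruvate isomerase (26.2 ± 4.24 against 0.611 ± 0.531, adjusted p = 0.0934), Erdr1 (676 ± 482 against 117 ± 29.2, adjusted p = 0.286) and Rab35, a small GTPase (58.9 against 18.8, adjusted p = 0.312). Hyi passed without the libraries that stood apart (log2 3.95, adjusted p = 0.00718) and with the term for them (0.0413), both chosen after the data were seen, and not without any 1 of the 6 libraries. Lower without passing were Lipo1 (4.56 against 13.4, adjusted p = 0.305), Tcf7, a Wnt pathway transcription factor of T lineage cells (0.858 ± 1.07 against 7.41 ± 2.72, adjusted p = 0.312) and Ankrd6 (1.54 against 6.39, adjusted p = 0.312).

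Of 31 gene lists 8 passed, and 0 with an estimated correlation. T and NK cell markers were lower, with a median log2 change of -1.17 (adjusted p = 2.01e-11; adjusted p = 0.263 with an estimated correlation). As a list mean on the log2 scale they lay at 1.59 to 1.92 in EAP and 1.67 to 2.27 in untransplanted WT. Transplanted WT, at 2.45 to 3.39, lay above both, so EAP was not set apart from untransplanted WT on this list. Cd8b1 was 0.706 ± 0.624 against 7.23 ± 4.37, Ncr1 was 0.502 against 4.52 and Cd3g was 0.929 against 3.56; 0 members passed over all genes and 1 adjusted over the list alone. B cell markers (-0.94, adjusted p = 4.06e-05) and type I interferon response genes (-0.43, adjusted p = 8.86e-06) were also lower, with an adjusted p of 0.380 for both with an estimated correlation. Blnk, a B cell receptor adaptor, was 5.57 ± 2.95 against 14.9 ± 6.81, and Irf7, an interferon regulatory factor, was 75.5 against 124. Their means ranged from -1.15 without transplanted WT 1 to -0.47 without transplanted WT 2 for B cell markers, and from -0.59 without transplanted WT 3 to -0.26 without transplanted WT 1 for interferon response genes. Of these lists 0 members passed over all genes and 0 adjusted over the list alone. MHC class II genes (-0.58, adjusted p = 0.00147; 0.380 with an estimated correlation) were lower, with H2-Eb1 at 24.9 ± 7.30 against 79.0 ± 51.4, and lost the call without EAP 3 (0.0784) or transplanted WT 3 (0.0552). Their list mean was 6.115 to 6.696 in EAP, 5.428 to 6.45 in untransplanted WT and 6.413 to 7.365 in transplanted WT. B cell markers and interferon response genes lay lower in every EAP library than in every untransplanted WT library.

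Immediate early genes were higher, with a median of 0.93 (adjusted p = 1.28e-06; adjusted p = 0.408 with an estimated correlation). Fos was 3439 ± 2313 against 1145 ± 45.2, Klf6 was 307 ± 113 against 89.0 ± 20.7 and Junb was 1083 ± 595 against 504 ± 143. The list did not pass without EAP 2 (mean change 0.47, adjusted p = 0.0627), the library with Egr1 at 840. Monocyte and macrophage markers were lower as a list (-0.21, adjusted p = 0.0330; 0.380 with an estimated correlation) although Cd14 rose; C1qb, a complement gene of macrophages, was 3.38 ± 1.84 against 12.1 ± 2.05 and C1qc was 2.18 against 12.3. In this list 1 member passed over all genes and 4 adjusted over the list alone, of which 3 were lower. Its call was lost without EAP 2 (0.498), EAP 3 (0.161), transplanted WT 2 (0.186) or 3 (0.0828). Erythroid markers (-0.29, adjusted p = 0.0225; 0.380 with an estimated correlation) were lower, and the call was lost without EAP 2 (0.147), EAP 3 (0.146), transplanted WT 2 (0.111) or 3 (0.332). Oxidative phosphorylation genes (-0.31, adjusted p = 0.0322; 0.746 with an estimated correlation) were lower, lost the call without EAP 3 (0.277) or transplanted WT 3 (0.789), and turned to 0.16 without EAP 2 (0.152). p53 targets (median -0.03, mean 0.09, tested as higher, adjusted p = 0.478), Wnt and beta-catenin targets (-0.27, adjusted p = 0.131) and DNA repair genes (-0.08, adjusted p = 0.955) did not pass.

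EAP with ENU was set against EAP without ENU to ask what mutagen exposure of donor and recipient added. No gene passed with limma (0 of 11730), 617 had an unadjusted p under 0.05, and 12.7% were fully separated against 10% by chance. Ccr2, the chemokine receptor of inflammatory monocytes, stood at 39.0 ± 19.8 against 6.49 ± 0.829 (SD, n = 3 each; log2 2.30 ± 0.38, SE), and Pf4, platelet factor 4, at 102 ± 29.8 against 33.3 ± 17.9. Sdpr stood at 16.1 against 3.46 and Enoph1 at 66.6 against 32.1. The heat shock genes Hspa1b (27.2 ± 25.3 against 592 ± 304; log2 -4.85 ± 0.91) and Hspa1a (16.8 ± 16.2 against 343 ± 183) were lower. So were Rsrc2 (13.9 against 53.5) and Atat1, a tubulin acetyltransferase (14.3 against 35.1). All 8 had an adjusted p of 0.696. Ces2g (21.2 against 6.84, adjusted p = 0.714) and Armc7 (18 against 39.6, adjusted p = 0.736) came next.

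Of 31 lists 9 passed, and 0 with an estimated correlation. Immediate early genes were lower with ENU, with a median of -1.37 (adjusted p = 3.85e-07; adjusted p = 0.358 with an estimated correlation). Fos was 831 ± 794 against 3439 ± 2313, Dusp1, a stress-induced phosphatase, was 433 ± 380 against 2522 ± 1274, and Klf6 was 84.6 against 307; 0 members passed over all genes and 2 adjusted over the list alone. Erythroid markers were higher (0.49, adjusted p = 0.000566; 0.226 with an estimated correlation), with Car1, a carbonic anhydrase, at 253 ± 92.3 against 74.3 ± 15.1 and Aqp1 at 36.2 ± 8.61 against 15.3 ± 2.69. In it 0 members passed over all genes and 2 adjusted over the list alone. These calls held without each of the 6 libraries, but the mean of the immediate early genes ranged from -1.91 without EAP with ENU 1 to -0.71 without EAP 2 (adjusted p = 0.0358). EAP 2 also had the lowest share of ribosomal protein transcripts (2.28%) of the LSK libraries. As list means, immediate early genes overlapped, at 5.29 to 7.47 in EAP with ENU and 6.26 to 8.37 in EAP. Erythroid markers did not, at 3.83 to 4.22 and 3.34 to 3.69. Transplanted WT, at 6.13 to 6.57 and 3.41 to 4.11, overlapped EAP with ENU on both lists. Against it neither list passed with all libraries (adjusted p = 0.236 and 0.113 with camera), though each did in some other fits.

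6 further lists were higher and lost their call without EAP 2. Myeloid progenitor granule genes had a median of 0.98 (adjusted p = 0.000744, and 0.298 without EAP 2). Their mean ranged from 0.34 without EAP 2 to 1.42 without EAP 1, which stood apart and, at a list mean of 7.70, lay above the 3 libraries with ENU (6.99 to 7.60). Members included Csf1r at 46.6 ± 16.5 against 13.8 ± 4.38, Plac8 at 3053 ± 335 against 1577 ± 802 and Cebpa at 25.2 against 11.9. Monocyte and macrophage markers had a median of 0.56 (adjusted p = 0.000744, and 0.202 without EAP 2), with Ly6c2 at 112 ± 19.6 against 8.75 ± 14.9 and Cx3cr1 at 6.29 against 2.39. Megakaryocyte markers had a median of 0.76 (adjusted p = 0.00595, and 0.0501 without EAP 2), with Itgb3 at 10.5 against 3.07 and Gp1bb at 11 against 4.05. With an estimated correlation the adjusted p of these 3 was 0.358, 0.226 and 0.226; 0, 0 and 0 members passed over all genes, and 0, 1 and 1 adjusted over the list alone. Cholesterol synthesis (0.37, adjusted p = 0.0111), antioxidant and NRF2 targets (0.26, 0.0175) and histone transcripts (0.42, 0.0173) gave 0.645, 0.898 and 0.298 without EAP 2. These had an adjusted p of 0.358, 0.477 and 0.358 with an estimated correlation. Histone transcripts also lost the call without EAP with ENU 1 (0.0980). T and NK cell markers (0.53, adjusted p = 0.0416; 0.736 with an estimated correlation) lost it without EAP with ENU 1 (0.374), EAP with ENU 3 (0.0743), EAP 2 (0.0629) or EAP 3 (0.631). p53 targets (-0.09, adjusted p = 0.244) and DNA repair genes (0.04, adjusted p = 0.985) did not pass. Neither did oxidative phosphorylation genes (0.0967) or eosinophil, basophil and mast cell markers (0.119). Without EAP 1, which stood apart, both of these passed as higher (means 0.70 and 1.17, adjusted p = 7.79e-10 and 5.82e-05). DNA replication genes did so too (mean 0.21, adjusted p = 0.0482).

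EAP with ENU was also set against transplanted WT, the same control libraries as for EAP. Cd14 rose from 0.913 ± 0.0895 to 24.2 ± 9.20 (SD, n = 3 each), a log2 change of 3.65 ± 0.41 (SE, adjusted p = 0.0198), and Mettl7a3 lay at 4.54 to 5.91 in EAP with ENU and was listed at 0 in transplanted WT (adjusted p = 0.0284). These 2 of 11730 genes passed, 376 had an unadjusted p under 0.05, and 18.5% were fully separated against 10% by chance. Cd14 passed without EAP with ENU 1 (0.0295) and not without EAP with ENU 2 (0.191) or 3 (0.194) or transplanted WT 1 (0.190), 2 (0.0865) or 3 (0.155). Mettl7a3 did not pass without any of the 6 (0.149 to 0.237). With a pseudocount of 0.1 Cd14 gave 0.0595, and with a replicate block Mettl7a3 gave 0.111. Hyi (22.8 ± 6.36 against 0.611, adjusted p = 0.205), Erdr1 (603 ± 111 against 117, 0.287) and Rab35 (62.6 against 18.8, 0.287) did not pass. Neither did the lower Wdfy1 (40.0 against 80.6, adjusted p = 0.357), Gstm7 (2.06 against 6.57, 0.417), Eaf2 (12.6 ± 3.61 against 30.2, 0.573) and Lipo1 (5.60 against 13.4, 0.732). Hyi (0.00735) and Rab35 (0.0360) passed without the libraries that stood apart, and Hyi and Wdfy1 with the term for them (0.0490 each). In a fit of these 2 groups alone Hyi (0.0202), Erdr1 and Rab35 (0.0253 each) passed. Whether the change differs between EAP with and without ENU in Eaf2, which passed in one of them, was not established, since the direct comparison did not call it.

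Of 31 lists 7 passed, and 0 with an estimated correlation. Myeloid progenitor granule genes were higher (1.19, adjusted p = 3.76e-07; 0.307 with an estimated correlation), with Ctsg at 843 ± 188 against 317 ± 50.3, Prtn3, proteinase 3, at 997 ± 240 against 435 ± 50.8, Csf1r at 46.6 against 16.4 and F13a1 at 91.4 ± 47.3 against 18.7 ± 7.20. Histone transcripts were higher (0.44, adjusted p = 0.00530; 0.307 with an estimated correlation), with Hist1h2ae at 253 against 140. Both lists passed without each library, with a mean of 0.29 instead of 0.49 for histone transcripts without transplanted WT 3. T and NK cell markers (-0.49, adjusted p = 2.15e-05), MHC class II genes (-0.67, adjusted p = 0.000468) and B cell markers (-0.58, adjusted p = 0.00104) were lower, with Lck, a T cell receptor kinase, at 52.8 ± 17.6 against 127 ± 48.9 and Cd74 at 374 against 1144. With an estimated correlation these gave 0.307, 0.307 and 0.487, and without transplanted WT 2 they gave 0.116, 0.0708 and 0.224. In each of these lists EAP with ENU overlapped untransplanted WT, at a list mean of 1.83 to 2.61 against 1.67 to 2.27 for T and NK cell markers. Interferon response genes (-0.17, adjusted p = 0.00530; 0.488 with an estimated correlation) were lower, with Ifit3 at 3.50 ± 1.28 against 9.79 ± 1.84, and lost the call without transplanted WT 1 (0.204) or 2 (0.165). Megakaryocyte markers (0.35, adjusted p = 0.00530; 0.307 with an estimated correlation) were higher, with Vwf at 10.6 against 2.92, and lost it without EAP with ENU 2 (0.106) or transplanted WT 2 (0.105). In these 7 lists 0 members passed over all genes and 0 adjusted over the list alone. p53 targets (-0.03, adjusted p = 0.451) did not pass.

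WT 2, transplanted WT 3 and EAP 1 stood apart from the other LSK libraries, at 67.7, 51.1 and 96.4 on a first principal component that held 49.8% of the variance, where the other 9 lay at -38.2 to -10.5. B cell markers were 1.26 higher in WT 2, and lymphoid priming genes fell by 1.42 there, on the log2 scale against the other libraries of its group. Myeloid granule genes were 1.77 higher in EAP 1. WT 2 had Ddx3y at 0.0415 and Eif2s3y, Uty and Kdm5d listed at 0, while the other 11 LSK libraries had Ddx3y at 14.3 to 55.5; these genes lie on the Y chromosome, and the sex of the mice is not in the labels.

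**Figure D2:**
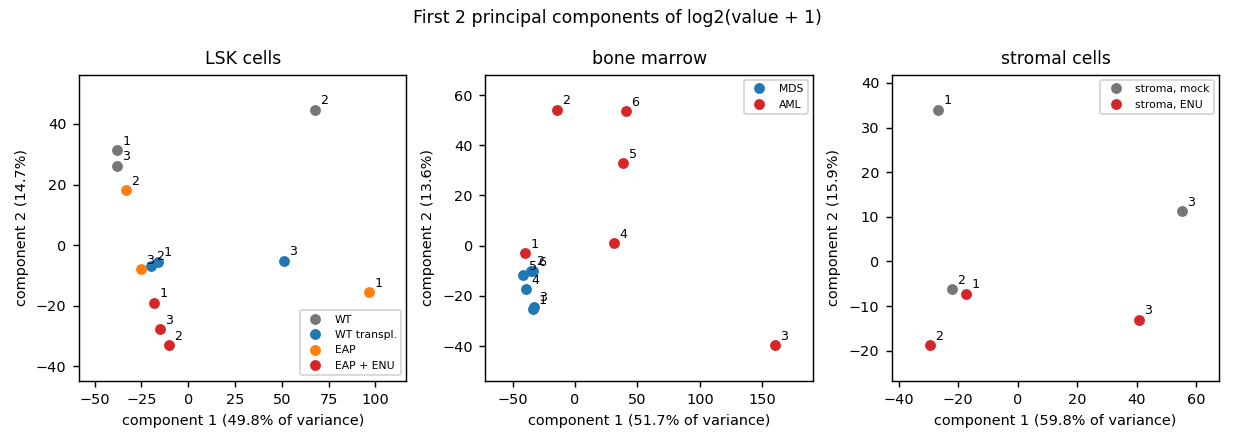
First and second principal components of log2(value + 1), unitless, for LSK, bone marrow and stromal cell libraries in a panel each, with colours for groups and numbers for replicates. WT 2, transplanted WT 3 and EAP 1 lie at 51.1 to 96.4 on the first LSK component and the other LSK libraries below -10.

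AML marrow was set against MDS marrow to ask what separates the diseases. The labels tie AML to the Trp53 shRNA and MDS to the luciferase shRNA, and ENU exposure differed between the diseases. All MDS libraries had ENU to donor and recipient. So did AML 1, 4 and 5, while AML 6 had it as recipient only and AML 2 and 3 had none. Erythroid markers were lower in AML as a list (median -3.58, adjusted p = 9.28e-11; adjusted p = 0.669 with an estimated correlation). Among single genes, Erfe, the hormone erythroferrone made by erythroblasts, fell from 163 ± 116 to 17.9 ± 21.1 (SD, n = 6 each), a log2 change of -3.63 ± 0.67 (SE, adjusted p = 0.0370). Rhag, a red cell membrane glycoprotein, fell from 413 ± 225 to 54.1 ± 55.9 (-3.83 ± 0.92, adjusted p = 0.0466). Lipg, endothelial lipase, fell from 118 ± 18.9 to 15 ± 20.6 (-4.12 ± 0.78, adjusted p = 0.0381). Tspan33 fell from 343 ± 117 to 55.0 ± 61.1 (adjusted p = 0.0499), Cldn13 from 160 to 26.5 (0.0473) and Slc38a5, a glutamine transporter, from 80.7 to 11.9 (0.0423). Rsad2, an interferon-induced antiviral gene, fell from 721 ± 602 to 92.7 ± 114 (0.0466).

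Higher in AML were the phosphatases Dusp5 (32.8 ± 14.5 against 7.0 ± 2.84, log2 2.05 ± 0.35, adjusted p = 0.0336) and Dusp2 (178 ± 136 against 33.5 ± 13.3, 2.12 ± 0.49, adjusted p = 0.0435), which switch off MAP kinases. Hdac7, a class IIa histone deacetylase, rose from 63.7 ± 8.61 to 234 ± 149 (1.59 ± 0.38, adjusted p = 0.0466), and Ralgds from 7.42 to 25.8 (0.0423). Sytl2 rose from 1.88 ± 0.879 to 34.0 ± 34.4 (adjusted p = 0.0499), Zfhx2 from 3.43 to 18.8 (0.0423), Snap47 from 4.79 to 23.9 (0.0458) and Nipsnap1 from 6.05 to 29.5 (0.0464). These 15 were separated with no overlap, as were 433 genes (3.84%, against 0.216% by chance). In all, 361 of 11273 genes passed, 112 higher and 249 lower, and 3302 had an unadjusted p under 0.05. edgeR on recovered reads called 448, of which 295 were higher and 153 lower and 253 were shared with limma's.

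The count rested on single libraries. It was 2475 without AML 1, 644 without AML 2, 267 without AML 3, 334 without AML 4, and 0 without AML 5, AML 6, MDS 1, 2, 3, 5 or 6, and 1 without MDS 4. Erfe went to adjusted p = 0.0663 to 0.102 in the settings where 0 or 1 genes passed, and its log2 change ranged from -4.10 to -3.33 over the 12. The 15 named genes passed in 2 to 4 of these 12 fits. With the 3 AML libraries exposed as MDS was, 0 genes passed and Erfe stood at -2.48 (adjusted p = 0.107), and without AML 3 to 6 it stood at -2.73 (0.121).

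Of 32 lists 9 passed, and 0 with an estimated correlation, which gave each an adjusted p of 0.669. Erythroid markers, lower as given above, had 4 of 17 members past the threshold over all genes and 17 adjusted over the list alone. Tfrc, the transferrin receptor, was 553 ± 347 against 2200 ± 1411, and Epor, the erythropoietin receptor, was 16.0 ± 16.7 against 81.5 ± 34.3. Late neutrophil markers were lower (-2.65, adjusted p = 5.34e-06; 0.669 with an estimated correlation), with 0 past the threshold over all genes and 13 adjusted over the list alone. Cxcr2, a neutrophil chemokine receptor, was 78.2 ± 104 against 252 ± 72.6 and the granule gene Camp was 1612 ± 2567 against 3916 ± 781. Ribosome biogenesis genes were higher (0.75, adjusted p = 5.34e-06; 0.669 with an estimated correlation), with 0 and 6 members; Nop56 was 149 ± 74.9 against 74.6 ± 6.17 and Ppan was 83.0 against 42.8. Mitosis genes were lower (-0.55, adjusted p = 0.000198; 0.669 with an estimated correlation), with 0 and 2 members; Ccna2, cyclin A2, was 155 ± 56.7 against 312 ± 87.9 and Mki67, which encodes Ki-67, was 1066 ± 406 against 2537 ± 1102. These 4 lists passed without each library in turn, though the mean went from -2.45 to -1.53 for late neutrophil markers without AML 3 and from -0.54 to -0.32 for mitosis without AML 2. Without AML 3 to 6, chosen after the data were seen, late neutrophil markers (0.214) and ribosome biogenesis genes (0.670) lost theirs, the latter turning to a mean of -0.0312.

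Myeloid progenitor granule genes (-1.75, adjusted p = 0.00103), with Cebpe at 62.2 ± 65.7 against 135 ± 43.3 and Fcgr3 at 119 against 267, and eosinophil, basophil and mast cell markers (-0.84, adjusted p = 0.00973), with Mcpt8 at 10.0 ± 7.63 against 31.3 ± 11.6, were lower and passed without each library in turn, but not without AML 3 to 6 (0.263 and 0.0727). In the fit without AML 3 to 6 the mean of myeloid granule genes turned to 0.21. Without AML 3 the means of both lists went from -1.57 to -0.74 and from -1.11 to -0.70. Their estimated correlation gave 0.669, over all genes 0 and 0 members passed, and adjusted over the list alone 0 and 3. Monocyte and macrophage markers (-0.88, adjusted p = 0.00651; 0.669 with an estimated correlation) were lower and lost the call without AML 3 (0.0876); Vcam1, an adhesion molecule of marrow macrophages and stroma, was 23.5 ± 12.8 against 69.6 ± 15 and passed over all genes (adjusted p = 0.0473) and adjusted over the list alone. The mean of monocyte and macrophage markers turned to 0.35 without AML 3 to 6. Antioxidant and NRF2 targets (-0.84, adjusted p = 0.0217; 0.669 with an estimated correlation) turned to a mean of 0.0397 without AML 3 to 6 and lost the call without AML 6 (0.0567). MHC class II genes (-1.27, adjusted p = 0.0468; 0.669 with an estimated correlation) lost it on rescaling (0.0562) and without AML 1, 2 or 5 or MDS 1, 2, 4, 5 or 6 (0.0575 to 0.108). T and NK cell markers (1.17, adjusted p = 0.173), B cell markers (median 0.04, mean -0.19, tested as lower, adjusted p = 0.364), Wnt and beta-catenin targets (0.99, adjusted p = 0.234), p53 targets (0.05, adjusted p = 0.859) and DNA repair genes (0.32, adjusted p = 0.267) did not pass. Without AML 3, T and NK cell markers (adjusted p = 0.00171) and Wnt targets (0.0409) passed as higher and B cell markers (mean -0.56, 4.21e-05) as lower, the last also without AML 3 to 6 (-0.35, 0.00886). DNA repair genes passed as higher without AML 2 (mean 0.41, adjusted p = 0.0227) and as lower without AML 3 to 6 (-0.41, 0.000878), so their direction hung on the libraries kept. The only 2 haemoglobin genes listed for bone marrow made up 0.0825 ± 0.0828% of AML values and 0.381 ± 0.151% of MDS values (exact permutation p = 0.00433, and 0.108 adjusted over 25 such tests). Ribosomal protein transcripts made up 1.0 ± 0.15% and 0.783 ± 0.0884% (exact permutation p = 0.0130, adjusted 0.162).

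**Figure D3:**
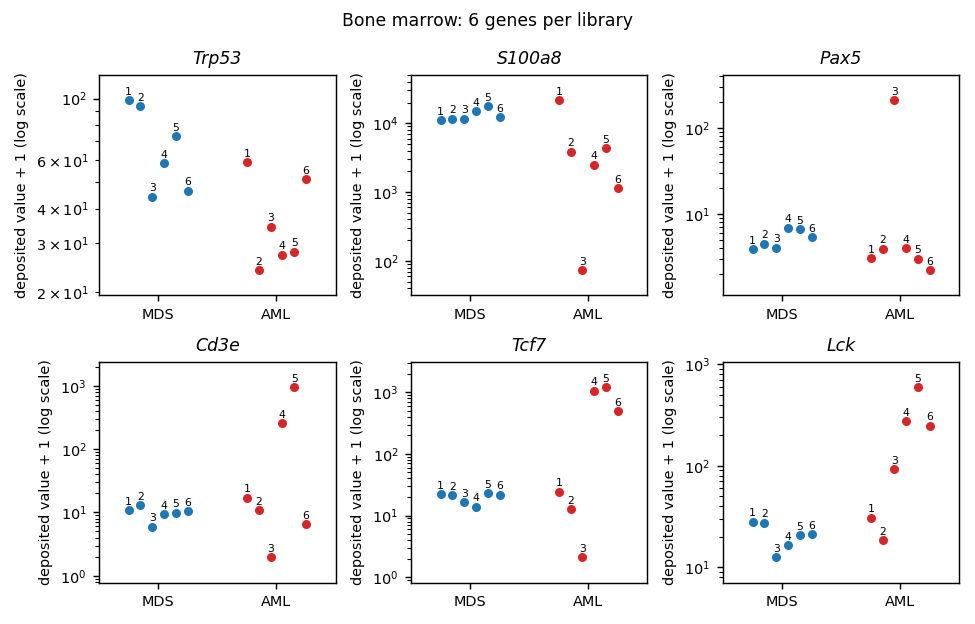
Deposited value + 1 on a log axis of Trp53, S100a8, Pax5, Cd3e, Tcf7 and Lck in each bone marrow library, with replicate numbers beside the points for MDS and AML. Tcf7 reaches 496 to 1207 in AML 4 to 6, and Pax5 208 in AML 3.

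Lymphoid genes set single AML libraries apart, as measured values not chosen as groups for a test. AML 3 had the B lineage genes Cd79a at 409, Pax5 at 208, Ebf1 at 420 and Vpreb3 at 258, with Dntt at 767, Il7r at 645 and Rag1 at 44.5, while Ms4a1, which encodes CD20, was 1.00. AML 4 had the T lineage genes Cd3e at 258, Tcf7 at 1070 and Ccr9 at 598, and Gzma at 237. AML 5 had Cd3e at 947, Tcf7 at 1207, Lck at 592, Notch1 at 1611, Rag1 at 586 and Dntt at 527. AML 6 had Tcf7 at 496, Lck at 246, Themis at 141 and Bcl11b at 73.8, with Cd3e at 5.52. Axin2, a direct Wnt target, was 105 in AML 4 and 174 in AML 5, and Myc was 247, 292, 177 and 150 in AML 3 to 6 against 48.9 to 68.2 in MDS. As a mean over the list on the log2 scale, T and NK cell markers were 6.02, 5.64 and 4.0 in AML 4 to 6 and 2.09 to 3.32 in MDS, and B cell markers were 5.37 in AML 3 and 3.22 to 4.06 in MDS. Erythroid markers were 7.33, 4.86, 1.42, 7.97, 6.06 and 4.45 in AML 1 to 6 and 8.15 to 10.02 in MDS. AML 1 lay close to the MDS libraries, at -39.8 on the first component where these lay at -41.5 to -32.8.

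**Figure D4:**
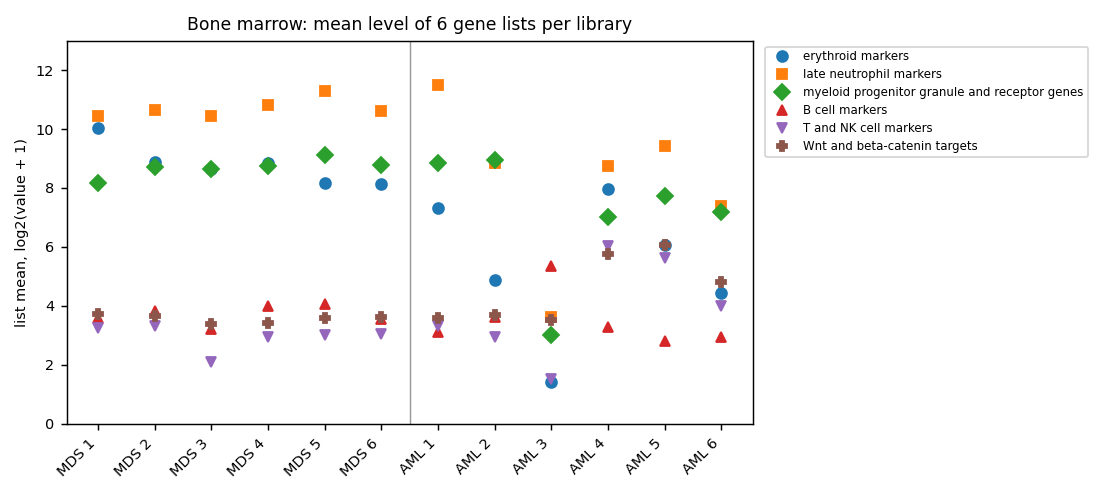
Mean log2(value + 1) over 6 gene lists (erythroid, late neutrophil, myeloid granule, B cell, T and NK cell, and Wnt genes) in each bone marrow library, with replicate numbers, for MDS and AML. Erythroid markers lie at 1.42 to 7.97 in AML and 8.15 to 10.02 in MDS, and T and NK cell markers reach 6.02 in AML 4.

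Within AML, the 3 libraries with ENU to donor and recipient (AML 1, 4 and 5) were set against the 2 without ENU (AML 2 and 3), the comparison the labels allow for mutagen exposure in the AML of this model. Ddx3y, on the Y chromosome, was lower in AML 2 and 3 than in AML 1, 4 and 5. Exposure thus goes with Y-linked values here, and the sex of the mice is not in the labels. Ca1, a red cell carbonic anhydrase, was 165 ± 95.6 (SD, n = 3) against 7.71 ± 10.6 (n = 2), a log2 change of 5.05 ± 0.91 (SE, adjusted p = 0.0477), and Aqp1, the red cell water channel, was 301 ± 163 against 17.2 ± 19.7 (4.53 ± 0.74, adjusted p = 0.0359). Slc40a1, the iron exporter ferroportin, was 159 against 6.39 (adjusted p = 0.0323), Cd33, a myeloid sialic acid receptor, 163 against 6.62 (0.0347), Mmp25, a neutrophil protease, 166 against 2.84 (0.0343), and Prss34, a basophil and mast cell protease, 26.9 against 0.878 (0.0323). Adam19 was 227 against 7.02 (0.0323) and Col5a1 54.1 against 2.62 (0.0303). Lower with ENU were Tbc1d30 (0.719 ± 0.150 against 8.19 ± 0.330, log2 -2.42 ± 0.26, adjusted p = 0.00917), Itga4, the integrin alpha 4 chain (247 ± 87.6 against 1134 ± 153, -2.26 ± 0.34, adjusted p = 0.0323), and Mreg (2.27 against 72.0, 0.0303). Tifa (27.9 against 143, 0.0323), Fam43a (17.7 against 89.7, 0.0433), Nid2 (1.19 against 15.5, 0.0352) and Cacnb2 (1.17 against 14.7, 0.0423) were lower too. Without AML 4, Ca1 (0.110), Aqp1 (0.0907), Cd33 (0.0704), Mmp25 (0.0532), Prss34 (0.0853), Adam19 (0.0735), Mreg (0.0704), Tifa (0.0839), Fam43a (0.0824), Nid2 (0.0872) and Cacnb2 (0.0930) lost their calls. Without AML 5, Ca1 (0.0517), Tifa (0.0517), Fam43a (0.0542), Nid2 (0.0524) and Cacnb2 (0.0523) did so, and without AML 1 Ca1 did (0.0514), whose log2 change ranged from 3.17 without AML 3 to 6.94 without AML 2.

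In all 46 of 11275 genes passed, 32 higher and 14 lower, and 1414 had an unadjusted p under 0.05; 15% of genes were fully separated, against 20% by chance for 3 against 2. edgeR on recovered reads called 15. The count was 14 without AML 4, 47 without AML 5, 181 without AML 1, 239 without AML 3 and 2559 without AML 2, where the last 2 leave 1 library without ENU that is assumed to vary like the others. With AML 6, given ENU as recipient only, added to the exposed libraries, 11 genes passed.

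Of 32 lists 13 passed, and 0 with an estimated correlation. Erythroid markers were higher (median 4.17, adjusted p = 1.81e-18; 0.306 with an estimated correlation) with 2 members past the threshold over all genes and 16 adjusted over the list alone. They passed without each library, with a mean of 2.26 without AML 3 to 5.70 without AML 2. Epor was 28.0 ± 15.7 against 1.62 ± 2.09, and Gata1, the erythroid master regulator, 38.7 ± 18.4 against 3.01 ± 4.13. T and NK cell markers were higher (2.34, adjusted p = 1.44e-09; 0.315 with an estimated correlation), with 0 and 11 members; Cd3d was 223 ± 184 against 2.72 ± 3.58 and Cd3e 407 ± 483 against 5.44 ± 6.34. Megakaryocyte markers (1.46, adjusted p = 7.26e-07; 0.306 with an estimated correlation) were higher with 1 and 7 members, and Itgb3 was 62.8 ± 11.4 against 7.29 ± 7.67. Without each library in turn the means of both lists ranged from 2.05 to 3.60 and from 1.03 to 2.14, and both passed without each library that had ENU. A fit without AML 3 to 6 leaves 1 library against 1, so it cannot decide whether these calls hold. AML 4 and AML 5, both with ENU, carried T lineage genes, as given above. Leaving out 1 of them keeps the other, so exposure and T lineage genes cannot be told apart in this comparison.

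AML 3, 1 of the 2 libraries without ENU and the lowest in erythroid and neutrophil genes, decided several other lists. Late neutrophil markers (3.53, adjusted p = 3.47e-11; 0.422 with an estimated correlation; 0 and 14 members) gave 0.0561 without it, with Camp at 3013 ± 3249 against 134 ± 156. Eosinophil, basophil and mast cell markers (2.17, adjusted p = 5.03e-06; 0.306 with an estimated correlation; 1 and 5 members) gave 0.0929, and B cell markers (-2.16, adjusted p = 0.00368; 0.306 with an estimated correlation; 0 and 1 member) gave 0.0625. Cd79b was 21.7 ± 5.07 against 233 ± 268. Myeloid progenitor granule genes (2.08, adjusted p = 0.00353; 0.607 with an estimated correlation) and monocyte and macrophage markers (1.33, adjusted p = 0.0127; 0.619 with an estimated correlation) turned without AML 3 to means of -1.08 (0.000626) and -0.84 (0.0297), and lost the call without AML 1 (0.0984 and 0.214). Wnt and beta-catenin targets (0.99, adjusted p = 0.00997; 0.334 with an estimated correlation; 0 and 2 members) gave 0.135 without AML 3, 0.140 without AML 2 and 0.0511 without AML 4, with Tcf7 at 766 ± 647 against 6.39 ± 7.48. MHC class II genes (1.33, adjusted p = 0.0483; 0.607 with an estimated correlation) lost the call on rescaling (0.0539), without AML 1 (0.196) or AML 4 (0.182), and turned to -0.06 without AML 3 (0.945).

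AML 2 decided others. DNA replication genes (0.61, adjusted p = 0.000401; 0.607 with an estimated correlation) turned to -0.19 without it (0.291), and mitosis genes (0.35, adjusted p = 0.0268; 0.689 with an estimated correlation) to -0.51 (0.00701), with Mki67 at 1386 ± 260 against 676 ± 216. Mitosis genes also lost the call without AML 1 (0.0918) or AML 4 (0.179). Oxidative phosphorylation genes (0.27, adjusted p = 0.00376; 0.607 with an estimated correlation) gave 0.821 without AML 2 and 0.0589 without AML 4. p53 targets (-0.11, adjusted p = 0.305) and DNA repair genes (0.23, adjusted p = 0.170) did not pass, though DNA repair genes passed as higher without AML 1 (mean 0.56, adjusted p = 0.00251) and without AML 3 (0.88, 5.41e-06).

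Stromal cells grown from mice given ENU were set against those from mock-treated mice, given 10% ethanol, to ask whether the mutagen left a change in the cells that form the marrow environment. No gene passed with limma (0 of 12089), and 312 had an unadjusted p under 0.05. Of the genes, 7.07% were fully separated, against 10% by chance if the libraries were exchangeable. The likeness of same-numbered libraries leaves that in doubt. The named genes all had an adjusted p of 1.00. Serpina3n, an acute phase protease inhibitor, stood at 23.1 ± 10.1 against 105 ± 13.9 (SD, n = 3 each; log2 -2.22 ± 0.32, SE), and C1s1, a complement protease, at 70.3 ± 15.4 against 185 ± 17.4 (-1.40 ± 0.17). Acp5, a gene of osteoclasts and macrophages (4.74 against 11.8), and Kdm1a (7.78 against 16.1) were lower. Pgd, of the pentose phosphate pathway, stood at 122 ± 9.0 against 79.5 ± 2.04 (0.60 ± 0.09), Fgd3 at 25.5 against 11, Gprc5c at 18.1 against 7.25, Acot7 at 97.0 against 66.1 and Pdgfa at 64.0 against 41.3.

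Of 28 lists 8 passed, and 0 with an estimated correlation, which gave each an adjusted p of 0.973. Cholesterol synthesis genes were lower (median -0.76, adjusted p = 4.55e-07; 0.973 with an estimated correlation), with Msmo1 at 98.4 ± 48.0 against 168 ± 38.9, Fdft1 at 28.9 ± 11.8 against 48.9 ± 8.48, Lss at 16.0 against 24.4 and Dhcr7 at 13.5 against 22.0. Osteoblast genes were higher (0.64, adjusted p = 0.000298; 0.973 with an estimated correlation), with Bglap2, which encodes osteocalcin, at 33.4 ± 12.7 against 15.9 ± 0.950, Dlx5 at 17.1 ± 5.13 against 10.5 ± 0.992 and Sp7, the osteoblast factor osterix, at 54.4 against 29.1. Both passed without each library, though the mean ranged from -1.01 without ENU 1 to -0.19 without ENU 3 for cholesterol synthesis, and from 0.28 without mock 3 to 0.97 without ENU 3 for osteoblast genes. A term for sex, chosen after the data were seen, cannot separate sex from treatment. Ddx3y, on the Y chromosome, was near 0 only in mock 1 and mock 2, so the term leaves ENU against mock 3 alone. Cholesterol synthesis and osteoblast genes each had 0 members past the threshold over all genes and 0 adjusted over the list alone. p53 targets were higher by a small median (0.17, adjusted p = 9.75e-05; 0.973 with an estimated correlation), with Polk, a translesion DNA polymerase, at 16.5 ± 1.56 against 9.05 ± 3.73, Eda2r at 26.0 against 21, Bax at 279 ± 32.2 against 238 ± 7.87 and Sesn1 lower at 17.1 against 24.7. Their call was lost without ENU 3 (0.540), and their mean turned to -0.00741 with the term for sex. Ribosome biogenesis genes were higher (0.13, adjusted p = 9.75e-05; 0.973 with an estimated correlation), and lost the call without mock 3 (0.382).

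Mitosis (0.45, adjusted p = 0.0106) and DNA replication genes (0.23, adjusted p = 0.0409) were higher, with 0.973 for both with an estimated correlation. They turned to -0.29 (0.254) and -0.20 (0.288) without mock 3, and lost the call without ENU 1 (0.358 and 0.710) or ENU 2 (0.263 and 0.537); DNA replication also lost it on rescaling (0.0611). Adipocyte genes (-0.48, adjusted p = 0.0396; 0.973 with an estimated correlation) were lower, with Adipoq, adiponectin, at 134 ± 72.7 against 212 ± 136. They gave 0.0761 with the replicate block, 0.196 without ENU 1, 0.134 without ENU 2 and 0.0712 without mock 2, and turned to 0.04 without mock 1 (0.581). Antioxidant and NRF2 targets (0.20, adjusted p = 0.0409; 0.973 with an estimated correlation) had Pgd past the threshold adjusted over the list alone (0.0121) and not over all genes. They gave 0.270 with the replicate block, 0.0733 on rescaling, 0.163 without mock 1 and 0.222 without mock 2, and turned to -0.13 without ENU 3 (0.871). Niche factors (0.10, adjusted p = 0.817), senescence genes (-0.03, adjusted p = 0.726), extracellular matrix genes (-0.14, adjusted p = 0.236) and DNA repair genes (0.12, adjusted p = 0.260) did not pass. DNA repair genes passed as higher with the replicate block (0.0135), without ENU 3 (0.00133), without mock 1 (0.0118) and without both libraries numbered 3 (0.0156). Their mean was 0.76 with the sex term, which leaves ENU against mock 3 alone. Extracellular matrix genes passed as lower without ENU 1 (0.0141) and ENU 2 (0.0244). Mock 3 and ENU 3 stood apart on a first component with 59.8% of the variance, with mitosis genes at a mean log2 of 3.46 and 4.27 where the other 4 libraries had 5.47 to 5.93. Ddx3y was 0.219 and 0.201 in mock 1 and mock 2 and 68.1 to 87.0 in the other 4.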

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

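The tests of the length, the lineage markers, the lymphoid genes, the interval on chromosome 18 and the fits without the libraries that stand apart were chosen after the result was seen; the other splits of the libraries and the rescaling of the components were fixed before.

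In groups of 6, the gap of the highest or lowest library to its nearest neighbour was compared with the range of the group. 5 of 78 values lay past the limit, where chance passes about 1 in 20 groups, or 3.9 of 78. Apc in AML 1 was 73.7 against 122 to 150 in the other AML libraries (gap 0.708 of the range), and the 10 largest genes took 12.6% of AML 1 against 3.35 to 6.53% (0.657). Sytl2 in MDS 3 was 0.265 against 1.73 to 2.73 (0.711), Rhag in MDS 1 was 858 against 249 to 389 (0.639), and Tifa in MDS 5 was 31.4 against 44.6 to 54.8 (0.628). Gaps are on the log2 scale for genes.

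Other splits of the same libraries into groups of the same sizes were counted. For AML against MDS, 1 of 100 drawn splits, the real one, called as many genes. The real split called 361 and the highest other 23, which argues against an arbitrary grouping of these libraries. Chance is not excluded, since the splits take the libraries as exchangeable. AML libraries lay at -39.8 to 160 on the first marrow component and MDS libraries at -41.5 to -32.8. The count also fell away without some single libraries, as given above. For 3 against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 3 and 0 for transplanted against untransplanted WT (1 split as large) and 3 and 1 for EAP (1 split). They were 0 and 0 for EAP with ENU against EAP (10 splits) and 2 and 1 for EAP with ENU against transplanted WT (1 split). For stromal cells they were 0 and 0 (10 splits, which ignore any pairing by replicate number).

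WT 2, transplanted WT 3 and EAP 1 stood apart on the first LSK component, across 3 groups. All 3 stayed at one end after rescaling, at 67.3, 51.0 and 96.5 against 67.7, 51.1 and 96.4 before. Rescaling hardly moved values that were already normalised. It thus argues only against a leftover scale factor per library, not against other effects of normalisation. The 3 also had the highest totals of the LSK libraries (1130054, 1206739 and 1437201). Cells of 1 other lineage mixed into all 3 are argued against, since the highest rise of a lineage list shared by them was 0.154 on the log2 scale. Cells of a different lineage in each stay open: B cell markers were 1.26 higher in WT 2, eosinophil, basophil and mast cell markers 1.08 higher in transplanted WT 3 and 1.52 in EAP 1, and myeloid granule genes 1.77 in EAP 1. Across 9207 genes, deviations from the group's other libraries fell with transcript length in all 3 (Spearman rho -0.430, -0.397 and -0.518), against 0.105, -0.138 and 0.0868 in EAP with ENU and 0.287 and -0.287 in EAP 2 and 3, so a length-dependent difference in library quality may contribute. Genes are not independent replicates, what counted as a deviation was set after these were seen, and no biological explanation was tested.

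AML 3 had B lineage genes and AML 4 to 6 T lineage genes far above MDS. A swap with MDS is argued against, since 0 MDS libraries lay nearer to the mean of AML 2 to 6, but a wrong label of AML 1 alone is not, since it lay nearer to MDS (distance 51.2) than to AML 2 to 6 (104). Mature B cells mixed into AML 3 are argued against by MHC class II genes at a mean log2 of 3.04, below the 5.04 to 6.43 of MDS, and mature T cells in AML 5 by Cd4 and Cd8a at 1.37% of Cd3e (140 to 211% in MDS) and in AML 6 by Cd3e at 5.52, within the range of MDS. In AML 4 Cd4 and Cd8a reached 19.8% of Cd3e, so mature T cells stay open there, as do leukaemic cells that carry lymphoid genes, a biological explanation that was not tested.

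Between the 6 LSK libraries of EAP genotype and the 6 wild type ones, 84 of 11464 genes did not overlap, 28 higher and 56 lower, where chance gives about 24.8. Strain-derived sequence around Egr1 and Apc, carried along with the targeted alleles, could change neighbouring genes. Of 82 placed genes 80 lay over 10 Mb from Egr1. The set holds Trp53, the shRNA target on chromosome 11, so the whole set could not have lain near Egr1. This count therefore says nothing on the interval as the source of a part. Psma8, Tmem241 and Pmaip1 of the set also lie on chromosome 18, at 20.2, 22.9 and 31.6 Mb from Egr1. The 2 within 10 Mb, Cd14 and Tmco6, made up 2.44% against 0.765% of other genes (one-sided Fisher exact p = 0.133), too few to be told apart from no enrichment. Among the 28 higher genes alone it was 7.14% against 0.761% (one-sided Fisher exact p = 0.0198). Both genes were higher and this subset was taken after the values were seen, so its p cannot decide the question. Cd14 and Tmco6 are also close neighbours, at 1.865 and 1.875 Mb from Egr1, while both tests take genes as independent. Whether the interval contributes stays open. In EAP with ENU against transplanted WT, the only compared library that stands apart is transplanted WT 3. Leaving out all that stand apart kept the calls of Cd14 and Mettl7a3 (adjusted p = 0.0196 and 0.0347). Leaving out transplanted WT 3 alone ended both (0.155 and 0.211). The log2 changes were 3.67 and 2.58 either way, against 3.65 and 2.58 with all libraries. This argues against these libraries as the source of the changes, though not of the calls, and the genotype itself stays open. In EAP leaving out the libraries that stand apart ended both calls (0.0640 and 0.107). The log2 changes went from 3.18 to 3.09 and from 2.52 to 2.23 with fewer libraries. With the term for these libraries, which moves only the spread here, both passed (0.00859 and 0.0128). Cd14 lay at 11.5 or more in all EAP genotype libraries and at 2.57 or less in all wild type ones. The changes thus did not rest on the libraries that stand apart alone, while the calls in EAP stay open.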

How the results depend on the processing

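The term for the LSK libraries that stand apart, the fits without libraries that stand apart or without AML 3 to 6, and the sex term were chosen after seeing the data; the other alternatives were planned. For every change below the cause was not tested, except that fits with fewer libraries have less power. edgeR was not run on LSK or stromal cells, where no reads were recovered.

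Of the 72 list calls 0 held with an estimated correlation, in each of the 7 comparisons. Without the libraries that stand apart the counts were 498 (transplanted WT), 1 (EAP), 1 (EAP with ENU against EAP) and 6 (EAP with ENU against transplanted WT), with a term for them 275, 6, 0 and 9 (in the first 2 each group holds 1 such library, so the term leaves the log2 changes as they were and moves only the spread), and in fits of only the compared groups 0, 0, 0 and 6. List counts for EAP with ENU against transplanted WT went from 7 to 14 with the term and 15 without the libraries. A pseudocount of 0.1 gave 1 gene there, 145 for AML against MDS and 108 for AML by exposure. AML against MDS gave 0 genes with only fully exposed AML and 0 without AML 3 to 6. AML by exposure gave 11 with recipient-only exposure included, 15 with edgeR (8 higher, 7 lower), and 504 genes and 8 lists without AML 3 to 6, which leaves 1 library against 1, assumed to vary like the others.

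With the replicate block, counts were 1 for transplanted WT, 0 for EAP, 1 for EAP with ENU against transplanted WT and 141 (6 higher, 135 lower) for AML against MDS. Numbers do not pair these libraries: same-numbered ones correlated at 0.309, -0.604 and -0.616 for transplanted WT, and not every library correlated best with its own number. In stromal cells, where each ENU library correlated best with the mock library of its number, the block gave 0 genes and 8 lists. It ended the calls of adipocyte genes and NRF2 targets. DNA repair genes (0.0135) and contractile and YAP target genes (0.00958) passed as higher with it.

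Leaving out 1 library gave 1 to 5 genes and 14 to 18 lists for transplanted WT, 0 to 1 and 4 to 11 for EAP, 0 to 0 and 2 to 12 for EAP with ENU against EAP, 0 to 1 and 2 to 12 for EAP with ENU against transplanted WT, 0 to 2475 and 8 to 11 for AML against MDS, 14 to 2559 and 10 to 15 for AML by exposure, and 0 to 3 and 6 to 11 for stromal cells (3 without mock 3).

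Egr1, Apc and Trp53 passed in no comparison as planned. Without AML 1, Trp53 (-1.05, adjusted p = 0.0216) and Apc (0.46, adjusted p = 0.0297) passed in AML against MDS, and with the term for the libraries that stand apart Trp53 passed in EAP with ENU against transplanted WT (-1.85, adjusted p = 0.0490). Several of their values turned on the log2 scale. Leaving out 1 library, Trp53 ranged from -0.18 to 0.20 (transplanted WT), -0.40 to 0.24 (EAP with ENU against EAP) and -0.0583 to 0.57 (AML by exposure), Apc from -0.41 to 0.0399 (EAP with ENU against EAP), and Egr1 from -1.16 to 0.0347 (EAP with ENU against transplanted WT), -1.13 to 0.43 (AML by exposure) and -1.03 to 0.72 (stromal cells). Trp53 was -0.0256 (transplanted WT) and -0.275 (EAP with ENU against EAP) without the libraries that stand apart, and in the latter -0.215 with the term and -0.00348 on rescaling. Apc was -0.0826 with the term (EAP with ENU against transplanted WT). Egr1 was 0.121 with recipient-only exposure included and 0.0258 without both stromal libraries numbered 3.

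List means that turned on leaving out 1 library ranged from -0.75 to 0.16 for oxidative phosphorylation in EAP. In AML by exposure they ranged from -1.08 to 4.87 (myeloid granule), -0.84 to 3.31 (monocyte), -0.51 to 1.36 (mitosis), -0.19 to 1.26 (DNA replication) and -0.0552 to 2.21 (MHC class II). In stromal cells they ranged from -0.29 to 0.97 (mitosis), -0.20 to 0.63 (DNA replication), -1.19 to 0.0434 (adipocyte) and -0.13 to 0.40 (NRF2 targets). Without AML 3 to 6, AML against MDS gave 0.21 (myeloid granule), 0.35 (monocyte), -0.0312 (ribosome biogenesis) and 0.0397 (NRF2 targets), and AML by exposure -0.11 (myeloid granule) and -0.0763 (Wnt targets). In stromal cells NRF2 targets were -0.0289 without both libraries numbered 3 and -0.0430 with the sex term, where p53 targets were -0.00741 and adipocyte genes 0.715. The sex term leaves ENU against mock 3 alone, so it cannot separate sex from treatment.

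Without a filter no gene call listed here turned. Depth is unknown for LSK and stromal cells, so a gene listed at 0, such as Mettl7a3, is not shown to be absent.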

Other observations

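The similarity of libraries was looked at without a planned test. WT 1 and WT 3 were the closest pair of LSK libraries by the median absolute log2 ratio (0.102 over 2417 genes, against 0.137 or more for the others) but not by Spearman correlation (0.985, against up to 0.989 for others). That all libraries come from separate mice is not given in the sources used here. In bone marrow Ddx3y, on the Y chromosome, was 68.0, 3.46, 0.574, 31.7, 84.4 and 145 in AML 1 to 6 and 15.1 to 130 in MDS. The values of AML 2 and 3, the libraries without ENU, lay below those of AML 1, 4 and 5. Exposure in AML thus goes with Y-linked values, and these cannot be told apart in that comparison. Ribosomal protein transcripts made up 2.28% of EAP 2, the library with Egr1 at 840, where immediate early genes had a mean log2 of 8.37. Between EAP with ENU and EAP this share was 6.31 ± 0.17% against 4.06 ± 1.70% (exact permutation p = 0.1, the smallest that 3 against 3 can give).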
